A study of Mus musculus with 30 samples.

How the data were processed

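The deposited files hold, for each of 30 libraries, kallisto transcript tables with estimated counts and TPM. The authors used kallisto 0.43.0 and genome build mm10, per the submitters' processing notes. The annotation release, strand and read layout were not stated. Every table lists 118491 targets. With GENCODE release M21 on mm10, 116816 of them matched a transcript including its version, 1673 did not match and were not used, and 2 were added sequences named GFP and mScarlet. Unmatched targets held 0.605 to 0.694% of the counts of a library. Estimated counts were summed per gene over 36047 genes and rounded to whole numbers.

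Gene tests used edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test with robust estimation, TMM scaling, and filterByExpr with a minimum count of 10 and a minimum total of 15). A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Groups of 1 experiment that share controls were fitted together, with group means and no replicate term. Log2 fold changes used a prior count of 0.125, and their standard error (SE) was derived from the F statistic. Levels are CPM with the standard deviation (SD) over 3 libraries. A fold against a group at 0 counts is a lower bound, taken against 3 counts over the group. Counting limits cover counting error only.

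Gene lists were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over 168 tests (28 lists in 6 comparisons). List medians and means are those of log2 fold changes. Where 2 adjusted p follow a median, the first is at the preset and the second at an estimated correlation. The 28 lists are Hedgehog target genes, Hedgehog pathway components, primary cilium assembly and transport, cholesterol synthesis and uptake, fatty acid synthesis and desaturation, sterol efflux and LXR targets, immediate early genes, reported Egr1 targets, reported AP-1 targets, epithelial genes, mesenchymal genes, extracellular matrix, TGF-beta and BMP targets, canonical Wnt targets and inhibitors, interferon response, NF-kB and inflammatory genes, cell cycle, p53 targets, integrated stress and unfolded protein response, glycolysis and hypoxia response, mitochondrially encoded genes, nuclear respiratory chain, adipocyte genes, cartilage and bone genes, muscle genes, immune cell markers, endothelial markers and neural markers. Of 53 calls at the preset correlation, camera kept 0 of 168 tests with an estimated correlation, where the lowest adjusted p was 0.239.

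The groups, tests, lists, alternatives and the rule for naming genes were set before the data were examined. The rule names, per comparison, the delivered factor, Gli1, Gli2, Gli3, Ptch1, Smo and Hhip where they pass the filter, the 8 rising and 8 falling protein-coding genes with the largest change (adjusted p under 0.05, at least 5 CPM in the higher group, no overlap between groups, no predicted name), and up to 4 called members of each list. Direct contrasts and the difference between experiments take 5 each way. GFP and mScarlet were added to the named items after the data were seen. Hhip passed the filter in no fit.

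For every gene the share of its transcript 31-mers found in no other gene was computed. Values of genes under 90% are uncertain, because reads may have been shared between near-identical sequences, and the share is printed beside them. DESeq2 1.42.0 served as the other test, and limma on log2(TPM + 1) for genes with a mean TPM of at least 1 (limma on TPM below) as another unit, test and filter at once. The stricter filter asks for at least 5 CPM in 3 libraries. The pipeline was tested on simulated data with 200 changed genes per comparison. At a 2-fold change it recovered 50.7% (difference between experiments) to 89.6% (Snai1 and Srebf2) of genes, and called 3 to 16 unchanged genes. Lists without simulated change had an unadjusted p under 0.05 in 2 to 5.5% of 200 draws, which leaves correlation within real lists open.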

Results

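RNA from NIH3T3-CG cells was sequenced. NIH3T3 is a mouse embryonic fibroblast line, and the labels do not explain the suffix. Bulk mRNA sequencing gave 30 libraries in 10 groups of 3 replicates. In 3 transfection experiments, cells received a plasmid for a transcription factor or a control plasmid. Prrx1 and Snai1 shared 1 set of controls, Egr1 and Jun shared another, and Srebf2 had its own. In a further experiment, cells transduced with Prrx1 were grown with or without doxycycline, the inducer of the construct. The series title places these factors in a study of how cells vary in their response to Hedgehog, and each comparison asks which genes follow a rise of 1 factor. No label states that a Hedgehog ligand was given. The origin of the replicates is not stated, so the p-values measure only the spread between these libraries, which may be technical.

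Depth, as total estimated counts, was 7996355 to 12600603 in the doxycycline libraries and 8506132 to 17129632 in those without. Prrx1 and Snai1 transfections held 18020141 to 20638309 and 18169803 to 19976799, and their controls 19574031 to 20961571. Egr1, Jun and their controls were deeper, at 29452035 to 37068611, 25329478 to 33085283 and 28567590 to 36470538. Srebf2 and its controls held 18572126 to 21352598 and 18976760 to 20379388.

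All 5 factors rose where they were delivered, by more than the spread between replicates in each of the 6 comparisons. Prrx1 (chromosome 1, 163245119 to 163313710, minus strand), a homeobox factor of limb and craniofacial mesenchyme, rose from 940.2 ± 75.4 CPM to 3526 ± 250.0 CPM with doxycycline (SD, n = 3), which is 3.85-fold (adjusted p = 3.08e-07). Transfection took it from 589.6 ± 87.5 to 16070 ± 2700 CPM, 27.5-fold (adjusted p = 2.74e-09). Snai1 (chromosome 2, 167538195 to 167542814, plus strand), a repressor of epithelial genes, went from 91.5 ± 3.71 to 11140 ± 626 CPM, 123-fold (adjusted p = 2.37e-12). Egr1 (chromosome 18, 34859823 to 34864984, plus strand), an immediate early zinc finger factor, went from 182 ± 24 to 1735 ± 241 CPM, 9.53-fold (adjusted p = 0.000368). Jun (chromosome 4, 95049034 to 95052222, minus strand), a subunit of AP-1, went from 198 ± 9.29 to 4407 ± 488 CPM, 22.1-fold (adjusted p = 1.34e-11). Srebf2 (chromosome 15, 82147181 to 82205379, plus strand), the main activator of sterol synthesis genes, went from 607 ± 17.1 to 2547 ± 159 CPM, 4.2-fold (adjusted p = 5.47e-14).

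**Figure D1:**
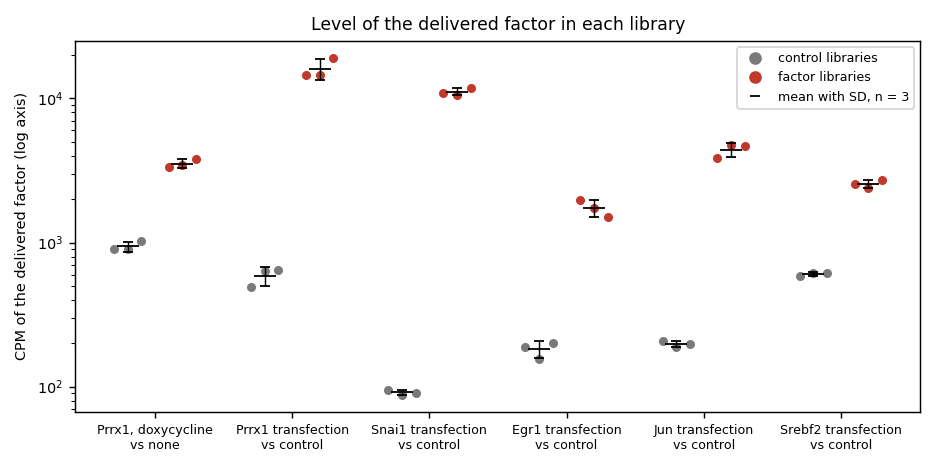
Level of the delivered factor in CPM on a log axis, 1 point per library, with the mean and SD of each group of 3. Each factor group lies above its control group.

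With doxycycline, the inducer of Prrx1, Gli2 (chromosome 1, 118834132 to 119053619), a transcription factor that carries the Hedgehog signal, rose from 20.8 ± 3.78 to 56.2 ± 2.82 CPM (SD, n = 3), 2.79-fold (log2 fold change 1.48 ± 0.138, adjusted p = 5.88e-05). The largest rise among named genes was that of Cck, the cholecystokinin hormone gene, at 37.8-fold (5.24 ± 0.563, adjusted p = 0.000169). In all, 844 of 13633 tested genes changed, 471 higher and 373 lower, 154 of them by over 2-fold. Groups did not overlap for 25.4% of tested genes, where chance gives 10%.

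Further rises were those of Adgrg1 (3.54), an adhesion receptor, Aldh1a7 (2.90, 86.2% unique 31-mers) and Aldh1a1 (2.43), aldehyde dehydrogenases, Prelp (2.77), a matrix proteoglycan, Ly6c1 (2.37, 53.2% unique 31-mers), a surface antigen, Ptx3 (2.35), a pentraxin, and Arnt2 (2.28), a bHLH-PAS partner. Cdh11 (1.87), a mesenchymal cadherin, Snai2 (1.22), a relative of Snai1, Thbs2 (1.13), a thrombospondin, and Vcam1 (0.88), an adhesion molecule, rose as well. The largest falls were those of Serpinb2 (−2.87, 88.8% unique 31-mers), a protease inhibitor, Cp (−2.61), ceruloplasmin, Tnfsf18 (−2.43), a TNF family ligand, Ccl9 (−2.25), a chemokine, and Brinp1 (−1.90). Ptgs2 (−1.43), cyclooxygenase 2, Postn (−1.60), periostin, and Col3a1 (−0.95), a fibrillar collagen, fell too.

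In cholesterol synthesis and uptake, 8 of 25 tested members rose and 17 did not pass (12 rose adjusted over the list alone), with median 0.26, adjusted p = 2.95e-06 and 0.239 with an estimated correlation. Its called enzymes include Ebp (0.71), Sqle (0.51) and Msmo1 (0.49), and its called regulator is Insig1 (0.47). For canonical Wnt targets and inhibitors, 4 of 9 tested members rose and 5 did not pass (5 rose adjusted over the list alone), with median 0.45, adjusted p = 0.000703 and 0.312 with an estimated correlation. They include the ubiquitin ligase Rnf43 (1.03), the ligand Wnt5a (0.90) and the inhibitors Dkk3 (0.86) and Apcdd1 (0.45). Among mesenchymal genes, 5 of 23 tested members rose, 2 fell and 16 did not pass (5 rose and 4 fell adjusted over the list alone), with median 0.10, adjusted p = 0.0173 and 0.582 with an estimated correlation, a call that ended without no-doxycycline replicate 3 (0.0779). Cdh11, Snai2 and the growth factor receptor Pdgfrb (0.79) are on the rising side and Col3a1 on the falling one.

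Among immediate early genes, which respond within minutes to stimuli, 1 of 26 tested members rose, 7 fell and 18 did not pass (2 rose and 11 fell adjusted over the list alone), with median −0.34, adjusted p = 0.0112 and 0.65 with an estimated correlation, a call that ended without no-doxycycline replicate 1 (0.0808). Fosb (−1.60), Ier2 (−0.98) and Zfp36 (−0.96) fell and Klf4 (1.16) rose. For reported AP-1 targets, 2 of 18 tested members rose, 5 fell and 11 did not pass (2 rose and 6 fell adjusted over the list alone), with median −0.29, adjusted p = 0.0296 and 0.582 with an estimated correlation, a call that ended without doxycycline replicate 1 (0.128) or no-doxycycline replicate 1 (0.0769), and also at the stricter filter (0.0715). Plau (−0.94), urokinase, and Spp1 (−0.69), osteopontin, fell, while Ccnd1 (1.32, 77.7% unique 31-mers), cyclin D1, rose. In the integrated stress and unfolded protein response, 3 of 30 tested members fell and 27 did not pass (3 fell adjusted over the list alone), with median −0.16, adjusted p = 0.00295 and 0.582 with an estimated correlation. The fallen genes are Chac1 (−0.65), Ddit3 (−0.53) and Pdia4 (−0.47). For glycolysis and hypoxia response, 4 of 29 tested members fell and 25 did not pass (10 fell adjusted over the list alone), with median −0.11, adjusted p = 0.00271 and 0.582 with an estimated correlation. These are Gapdh (−0.73, 71.9% unique 31-mers), Vegfa (−0.59), Pgk1 (−0.35, 45.3% unique 31-mers) and P4ha1 (−0.32). In the nuclear respiratory chain, edgeR called 0 of 34 tested members (0 higher and 4 lower at an unadjusted p under 0.05, 0 and 1 by DESeq2, 0 adjusted over the list alone), with median −0.17, adjusted p = 0.0342 and 0.811 with an estimated correlation, a call that ended without doxycycline replicate 1 (0.0758) or no-doxycycline replicate 1 (0.744, median −0.04), and also at the stricter filter (0.0589).

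Among Hedgehog pathway components, 3 of 34 tested members rose, 1 fell and 30 did not pass (3 rose and 1 fell adjusted over the list alone). Besides Gli2, the coreceptor Gas1 (0.88) and Mosmo (0.40), an inhibitor of Smo, rose, and the kinase subunit Prkaca (−0.37) fell. The list as a whole was not called (adjusted p = 0.379). The Hedgehog genes Gli1 (−0.52 ± 0.471, adjusted p = 0.605), Gli3 (0.07 ± 0.0934, adjusted p = 0.758), Ptch1 (0.20 ± 0.147, adjusted p = 0.516) and Smo (0.32 ± 0.14, adjusted p = 0.257) did not pass. The count of changed genes was 421 without doxycycline replicate 1, 335 without doxycycline replicate 2, 384 without doxycycline replicate 3 and 515 without no-doxycycline replicate 3. By limma on TPM 162 genes were called, 70.4% of them higher against 55.8% here, and a fit on all 30 libraries called 2728, 34.8% higher. Of 74 called genes that the naming rule chose, 41 kept their call with each library left out.

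With Prrx1 transfection, Sdk2, a cell adhesion protein of synapses, rose 20.5-fold (log2 fold change 4.36 ± 0.253, adjusted p = 9.21e-07, n = 3 per group). P2rx7, an ATP-gated channel, rose 3.89-fold (1.96 ± 0.172, adjusted p = 5.61e-05). mt-Nd1 (−0.91), a mitochondrially encoded complex I subunit with 100% unique 31-mers, fell. In all, 393 of 13110 tested genes changed, 254 higher and 139 lower, 76 by over 2-fold, and 151 of them have under 90% unique 31-mers. For 19.1% of tested genes the groups did not overlap, against 10% by chance.

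Vgf (1.35), a neuropeptide precursor, Notch1 (1.26), a signalling receptor, Kif5a (0.92), a neuronal kinesin, and Arc (0.78), an activity-induced gene, rose. Rbfox3, a neuronal splicing factor, was at 0 counts in the controls and at least 15-fold higher with Prrx1 (adjusted p = 0.00875). Nutf2 (0.94, 56.4% unique 31-mers), a nuclear transport factor, rose with shared sequence. Falls among matrix and mesenchymal genes were small, as for Ogn (−0.56), Bgn (−0.42) and Dcn (−0.35), small proteoglycans, and Snai2 (−0.51). Rps27rt (−1.41, 7.6% unique 31-mers), a ribosomal retrogene, and Ube2c (−0.49, 75% unique 31-mers), a mitotic ubiquitin enzyme, fell as well.

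In mitochondrially encoded genes, 11 of 13 tested members fell and 2 did not pass (13 fell adjusted over the list alone), with median −0.86, adjusted p = 1.36e-36 and 0.239 with an estimated correlation. Apart from mt-Nd1 they include mt-Nd5 (−0.89, 83.2% unique 31-mers), mt-Co2 (−0.98, 0% unique 31-mers) and mt-Atp6 (−0.93, 0.5% unique 31-mers). Their share of all counts was 1.225 ± 0.218% with Prrx1 and 2.171 ± 0.227% in the controls (SD, n = 3). Nuclear respiratory chain genes went the other way, and 6 of 34 tested members rose and 28 did not pass (14 rose adjusted over the list alone), with median 0.14, adjusted p = 7.51e-06 and 0.656 with an estimated correlation. Ndufa1 (0.66), Cox5b (0.63, 83.9% unique 31-mers) and Ndufa8 (0.55) are examples. Among p53 targets, 3 of 22 tested members rose and 19 did not pass (8 rose adjusted over the list alone), with median 0.12, adjusted p = 0.00109 and 0.312 with an estimated correlation. They are the cell death genes Bbc3 (0.54) and Bax (0.50, 88.9% unique 31-mers) and the nuclease Aen (0.36).

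Several list calls rested on small shifts. In cholesterol synthesis and uptake, 2 of 24 tested members fell and 22 did not pass (2 fell adjusted over the list alone), with median −0.07, adjusted p = 0.0296 and 0.582 with an estimated correlation, a call that ended without Prrx1 replicate 2 (0.0719), Prrx1 replicate 3 (0.134) or control replicate 2 (0.063), and also at the stricter filter (0.058). The fallen enzymes are Nsdhl (−0.32) and Msmo1 (−0.22). In fatty acid synthesis and desaturation, 1 of 19 tested members fell and 18 did not pass (2 fell adjusted over the list alone), namely Fads1 (−0.21), a desaturase, with median −0.08, adjusted p = 0.0342 and 0.65 with an estimated correlation, a call that ended without Prrx1 replicate 2 (0.0719), Prrx1 replicate 3 (0.11), control replicate 2 (0.21, median −0.03) or control replicate 3 (0.107). Among mesenchymal genes, 1 of 24 tested members fell and 23 did not pass (1 fell adjusted over the list alone), with median −0.08, adjusted p = 0.017 and 0.441 with an estimated correlation, a call that ended without Prrx1 replicate 3 (0.0862, median −0.05). In extracellular matrix, 3 of 34 tested members fell and 31 did not pass (1 rose and 8 fell adjusted over the list alone), with median −0.06, adjusted p = 0.0288 and 0.656 with an estimated correlation, a call that ended without Prrx1 replicate 1 (0.0533), Prrx1 replicate 3 (0.381, median −0.00), control replicate 2 (0.142) or control replicate 3 (0.335, median −0.02), and also at the stricter filter (0.058). For neural markers, 1 of 4 tested members rose and 3 did not pass (1 rose adjusted over the list alone), with median 0.34, adjusted p = 0.027 and 0.582 with an estimated correlation, a call that ended without Prrx1 replicate 2 (0.083), control replicate 1 (0.179) or control replicate 2 (0.0848), and also at the stricter filter (0.786, median 0.13). The risen neural marker is Rbfox3.

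The Hedgehog genes Gli1 (0.11 ± 0.21, adjusted p = 0.861), Gli2 (−0.03 ± 0.0925, adjusted p = 0.926), Gli3 (−0.10 ± 0.121, adjusted p = 0.734), Ptch1 (0.15 ± 0.145, adjusted p = 0.656) and Smo (−0.10 ± 0.0718, adjusted p = 0.541) did not pass. Left-out libraries moved the count strongly, to 143 without Prrx1 replicate 1, 153 without Prrx1 replicate 2, 106 without Prrx1 replicate 3, 2639 without control replicate 1, 199 without control replicate 2 and 165 without control replicate 3. A fit on all 30 libraries called 335 genes, 50.1% higher against 64.6% here. Of 42 called genes that the naming rule chose, 14 kept their call with each library left out.

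With Snai1, Hspa1a, an inducible HSP70 gene, rose 6.29-fold (log2 fold change 2.65 ± 0.113, adjusted p = 1.88e-08, n = 3 per group) and its near-identical neighbour Hspa1b 5.15-fold (2.36 ± 0.12, adjusted p = 1.36e-07), with 29.9% and 31.9% unique 31-mers. The RNA-binding protein gene Hnrnpa0 (0.81) rose, and mt-Nd1 fell (−0.88 ± 0.108, adjusted p = 0.00145). In all, 212 of 13110 tested genes changed, 149 higher and 63 lower, 22 by over 2-fold, and 108 have under 90% unique 31-mers. The groups were apart for 20.5% of tested genes, against 10% by chance.

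H2afj (1.06), a histone H2A variant, Prss22 (0.92), a serine protease, and Nutf2 (0.89, 56.4% unique 31-mers) rose. Smad7 (0.47), an inhibitor of TGF-beta signalling, Ddit4 (0.43), a stress gene that restrains mTOR, and Sdf2l1 (0.46), a cochaperone, rose less. Nudt14 (−0.89), a hydrolase, fell, as did Ube2c (−0.31, 75% unique 31-mers). Epithelial genes, the known targets of Snai1, were not called as a list (adjusted p = 0.634, median −0.10), and edgeR called 0 of 8 tested members (0 higher and 0 lower at an unadjusted p under 0.05, 0 and 0 by DESeq2, 0 adjusted over the list alone).

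In mitochondrially encoded genes, 12 of 13 tested members fell and 1 did not pass (13 fell adjusted over the list alone), with median −0.86, adjusted p = 5.19e-40 and 0.239 with an estimated correlation. They include mt-Nd3 (−1.05, 1.9% unique 31-mers), mt-Co2 (−0.97, 0% unique 31-mers) and mt-Nd6 (−0.97). Nuclear respiratory chain genes went the other way, and 6 of 34 tested members rose and 28 did not pass (11 rose adjusted over the list alone), with median 0.17, adjusted p = 4.46e-07 and 0.652 with an estimated correlation. Cox5b (0.65, 83.9% unique 31-mers), Ndufa8 (0.59) and Ndufs7 (0.45) are examples. For p53 targets, 1 of 22 tested members rose and 21 did not pass (4 rose adjusted over the list alone), namely Phlda3 (0.55), with median 0.13, adjusted p = 0.00767 and 0.418 with an estimated correlation. In primary cilium assembly and transport, edgeR called 0 of 45 tested members (2 higher and 4 lower at an unadjusted p under 0.05, 0 and 0 by DESeq2, 0 adjusted over the list alone), with median −0.09, adjusted p = 0.0247 and 0.582 with an estimated correlation, a call that ended without control replicate 2 (0.0674), control replicate 3 (0.0569) or Snai1 replicate 3 (0.0865). For the interferon response, edgeR called 0 of 27 tested members (7 higher and 0 lower at an unadjusted p under 0.05, 2 and 0 by DESeq2, 2 rose adjusted over the list alone), with median 0.23, adjusted p = 0.0288 and 0.656 with an estimated correlation, a call that ended without control replicate 1 (0.13), control replicate 2 (0.0543) or Snai1 replicate 2 (0.311), and also at the stricter filter (0.253, median 0.02) and with the replicate block (0.053). In the cell cycle list, 1 of 40 tested members fell and 39 did not pass (4 fell adjusted over the list alone), namely Ube2c, with median −0.06, adjusted p = 0.0459 and 0.658 with an estimated correlation, a call that ended without control replicate 2 (0.063, median −0.04), control replicate 3 (0.0884, median −0.03) or Snai1 replicate 2 (0.146), and also at the stricter filter (0.0672) and with the replicate block (0.053).

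As with Prrx1, the Hedgehog genes Gli1 (0.09 ± 0.211, adjusted p = 0.891), Gli2 (−0.09 ± 0.0929, adjusted p = 0.703), Gli3 (−0.03 ± 0.121, adjusted p = 0.946), Ptch1 (0.09 ± 0.146, adjusted p = 0.827) and Smo (0.01 ± 0.0717, adjusted p = 0.981) did not pass. The count of changed genes became 3062 without control replicate 1, 94 without control replicate 2, 57 without control replicate 3, 58 without Snai1 replicate 1, 78 without Snai1 replicate 2 and 46 without Snai1 replicate 3. A fit on all 30 libraries called 232 genes, 59.9% higher against 70.3% here. Of 26 called genes that the naming rule chose, 11 kept their call with each library left out.

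Compared directly, Snai1 and Prrx1 transfections differed in 33 genes, 4 higher and 29 lower with Snai1. Hspa1a (2.20, 29.9% unique 31-mers) and Hspa1b (2.17, 31.9% unique 31-mers) were higher with Snai1. Sdk2 (−4.52), P2rx7 (−2.04), Arc (−1.24) and Vgf (−0.97) were lower, and Rbfox3 at least 14-fold lower. The interferon list was higher with Snai1 (median 0.20, adjusted p = 0.00367 and 0.655), where edgeR called 0 of 27 tested members (5 higher and 0 lower at an unadjusted p under 0.05, 0 and 0 by DESeq2, 0 adjusted over the list alone). Neural markers were lower (median −0.34, adjusted p = 0.00367 and 0.367), and 1 of 4 tested members was lower and 3 did not pass (1 was lower adjusted over the list alone). Small shifts were called for mesenchymal genes (median 0.05, adjusted p = 0.0282 and 0.367 with an estimated correlation), where edgeR called 0 of 24 tested members (3 higher and 0 lower at an unadjusted p under 0.05, 0 and 0 by DESeq2, 0 adjusted over the list alone), and for extracellular matrix (median 0.08, adjusted p = 0.0251 and 0.755 with an estimated correlation), where edgeR called 0 of 34 tested members (3 higher and 0 lower at an unadjusted p under 0.05, 0 and 1 by DESeq2, 0 adjusted over the list alone). With 1 library left out, these calls held in 4, 6, 3 and 2 of 6 fits, in that order, with the interferon median at 0.048 without Snai1 replicate 2 and that of matrix at 0.011 without Prrx1 replicate 3. Groups did not overlap for 17.1% of genes, against 10% by chance. The count was 20 without Prrx1 replicate 1, 19 without Prrx1 replicate 2, 14 without Prrx1 replicate 3, 18 without Snai1 replicate 1, 19 without Snai1 replicate 2 and 11 without Snai1 replicate 3. Limma on TPM called 7 genes, 57.1% higher, and with a length offset 9, 33.3% higher, against 12.1% here.

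With Egr1, Nfkbie, an NF-kB inhibitor, rose 1.68-fold (log2 fold change 0.75 ± 0.0859, adjusted p = 0.00189, n = 3 per group), and Mx1, an interferon-induced GTPase, rose 3.37-fold (1.75 ± 0.247, adjusted p = 0.00931). The stress phosphatase regulator Ppp1r15a was 1.78-fold lower (−0.84 ± 0.0763, adjusted p = 0.000903). In all, 47 of 14539 tested genes changed, 30 higher and 17 lower, 15 by over 2-fold, and groups did not overlap for 15.6% of tested genes, against 10% by chance.

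Vmn1r88 (2.63, 72.3% unique 31-mers), annotated as a vomeronasal receptor, Cacnb1 (0.85), a calcium channel subunit, Sphk1 (1.29), a sphingosine kinase, and Il11 (1.13), a cytokine, rose. The Mx1 call ended without Egr1 replicates 1 (0.0528) and 2 (0.0607) or control replicate 1 (0.0679). Lower were Atp13a4 (−2.26), a cation pump, Dyrk3 (−0.57), a kinase, Txnip (−0.41), an inhibitor of thioredoxin, and Tnfaip3 (−0.39), an NF-kB inhibitor. Fosl1 (−0.40, 45.5% unique 31-mers), an AP-1 subunit, fell too. The reported Egr1 targets were not called as a list (median 0.04, adjusted p = 0.214), and edgeR called 0 of 19 tested members (3 higher and 1 lower at an unadjusted p under 0.05, 1 and 1 by DESeq2, 1 rose and 1 fell adjusted over the list alone).

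For p53 targets, 3 of 23 tested members fell and 20 did not pass (4 fell adjusted over the list alone), with median −0.10, adjusted p = 2.01e-05 and 0.312 with an estimated correlation. They are Mdm2 (−0.37), Plk2 (−0.26) and Ccng1 (−0.22). In fatty acid synthesis and desaturation, 1 of 19 tested members rose and 18 did not pass (1 rose adjusted over the list alone), namely Acaca (0.29, 66.6% unique 31-mers), acetyl-CoA carboxylase, with median 0.10, adjusted p = 1.29e-05 and 0.582 with an estimated correlation. In cholesterol synthesis and uptake, edgeR called 0 of 25 tested members (4 higher and 0 lower at an unadjusted p under 0.05, 0 and 0 by DESeq2, 0 adjusted over the list alone), with median 0.15, adjusted p = 1.15e-06 and 0.65 with an estimated correlation. For the interferon response, 1 of 33 tested members rose and 32 did not pass (1 rose adjusted over the list alone), namely Mx1, with median 0.31, adjusted p = 0.000131 and 0.656 with an estimated correlation, a call that ended without Egr1 replicate 1 (0.33, median 0.11). Mitochondrially encoded genes were shifted upward, although edgeR called 0 of 13 tested members (8 higher and 0 lower at an unadjusted p under 0.05, 3 and 0 by DESeq2, 6 rose adjusted over the list alone), with median 0.22, adjusted p = 6.09e-10 and 0.418 with an estimated correlation.

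In nuclear respiratory chain genes, edgeR called 0 of 34 tested members (0 higher and 7 lower at an unadjusted p under 0.05, 0 and 1 by DESeq2, 0 adjusted over the list alone), with median −0.06, adjusted p = 1.47e-05 and 0.65 with an estimated correlation. For the cell cycle, edgeR called 0 of 40 tested members (0 higher and 6 lower at an unadjusted p under 0.05, 0 and 1 by DESeq2, 0 adjusted over the list alone), with median −0.09, adjusted p = 3.92e-06 and 0.656 with an estimated correlation, a call that ended without Egr1 replicate 1 (0.266, median −0.02). In extracellular matrix, edgeR called 0 of 39 tested members (3 higher and 0 lower at an unadjusted p under 0.05, 1 and 0 by DESeq2, 0 adjusted over the list alone), with median 0.07, adjusted p = 0.000919 and 0.604 with an estimated correlation, a call that ended without control replicate 2 (0.397, median 0.03). Among epithelial genes, edgeR called 0 of 21 tested members (5 higher and 0 lower at an unadjusted p under 0.05, 1 and 0 by DESeq2, 3 rose adjusted over the list alone), with median 0.94, adjusted p = 0.000353 and 0.65 with an estimated correlation, a call that ended without Egr1 replicate 3 (0.128, median 0.14). For immune cell markers, edgeR called 0 of 6 tested members (0 higher and 1 lower at an unadjusted p under 0.05, 0 and 0 by DESeq2, 0 adjusted over the list alone), with median −0.45, adjusted p = 0.0462 and 0.536 with an estimated correlation, a call that ended without Egr1 replicate 1 (0.191), Egr1 replicate 2 (0.236), Egr1 replicate 3 (0.0613), control replicate 1 (0.106) or control replicate 2 (0.283, median −0.21), and also at the stricter filter (0.0863, median −0.24).

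Among Hedgehog genes, Gli1 (0.06 ± 0.246, adjusted p = 0.961), Gli2 (0.15 ± 0.114, adjusted p = 0.692), Gli3 (0.16 ± 0.0858, adjusted p = 0.575), Ptch1 (0.10 ± 0.065, adjusted p = 0.641) and Smo (−0.07 ± 0.042, adjusted p = 0.597) did not pass. Leaving out libraries gave 20 without Egr1 replicate 1, 10 without Egr1 replicate 2, 102 without Egr1 replicate 3, 15 without control replicate 1 and 16 without control replicate 3, and 355 without Egr1 replicate 3 and control replicate 2 together. By limma on TPM, where the median gene moved by 0.148, 1172 genes were called, 98.4% higher against 63.8% here. Without scaling between libraries, that shift of most genes is part of these calls. Of 21 called genes that the naming rule chose, 5 kept their call with each library left out.

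Jun raised Mmp10, a stromelysin and known AP-1 target, by 62.2-fold (log2 fold change 5.96 ± 0.973, adjusted p = 0.0154, n = 3 per group, 88.1% unique 31-mers), a call that ended in 6 of 11 alternatives, among them without control replicates 1 (0.0513) and 3 (0.0757) or Jun replicates 1 (0.08), 2 (0.0774) and 3 (0.114). Eng, a TGF-beta coreceptor, was 3.62-fold lower (−1.86 ± 0.188, adjusted p = 0.000655), and Id3, an inhibitor of bHLH factors that follows BMP signals, was 3.19-fold lower (−1.68 ± 0.204, adjusted p = 0.00223). Hmox1, heme oxygenase 1, fell (−0.61 ± 0.0724, adjusted p = 0.0038). In all, 139 of 14539 tested genes changed, 66 higher and 73 lower, 31 by over 2-fold. Groups did not overlap for 22.7% of tested genes, against 10% by chance.

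Mustn1 (0.92), a musculoskeletal gene, H1fx (0.69), a linker histone, Hes1 (0.65), a Notch target, and Npr3 (0.58), a natriuretic peptide receptor, rose. Hecw2 (−2.64), a ubiquitin ligase, Atp13a4 (−1.99), P2rx7 (−1.97), Dusp8 (−1.28), a MAP kinase phosphatase, Ppp1r15a (−0.85) and Maff (−0.42), a small Maf factor, fell. The reported AP-1 targets were not called as a list (median 0.02, adjusted p = 0.963), and 1 of 24 tested members rose, 2 fell and 21 did not pass (3 rose and 3 fell adjusted over the list alone).

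For p53 targets, 4 of 23 tested members fell and 19 did not pass (1 rose and 14 fell adjusted over the list alone), with median −0.19, adjusted p = 2.63e-12 and 0.239 with an estimated correlation. They are Pmaip1 (−1.31), a cell death gene, Eda2r (−0.58), Mdm2 (−0.53) and Plk2 (−0.24). In extracellular matrix, 1 of 39 tested members rose and 38 did not pass (6 rose adjusted over the list alone), namely Lum (0.51), lumican, with median 0.14, adjusted p = 3.13e-06 and 0.582 with an estimated correlation. Among mesenchymal genes, 1 of 24 tested members rose and 23 did not pass (3 rose adjusted over the list alone), namely Fn1 (0.31), fibronectin, with median 0.09, adjusted p = 0.000229 and 0.592 with an estimated correlation. Fn1 is also the risen member of the reported Egr1 targets, of which 1 of 19 tested members rose and 18 did not pass (5 rose and 2 fell adjusted over the list alone), with median 0.10, adjusted p = 0.00819 and 0.582 with an estimated correlation, although the mean was −0.03 and the test went upward. For endothelial markers, 1 of 8 tested members fell and 7 did not pass (1 fell adjusted over the list alone), namely Eng, with median −0.76, adjusted p = 0.0074 and 0.312 with an estimated correlation, a call that ended without control replicate 1 (0.0846, median −0.43) or Jun replicate 2 (0.065).

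In fatty acid synthesis and desaturation, 1 of 19 tested members rose and 18 did not pass (9 rose adjusted over the list alone), namely Acaca (0.25, 66.6% unique 31-mers), with median 0.12, adjusted p = 2.95e-06 and 0.582 with an estimated correlation. In cholesterol synthesis and uptake, edgeR called 0 of 25 tested members (9 higher and 1 lower at an unadjusted p under 0.05, 2 and 0 by DESeq2, 0 adjusted over the list alone), with median 0.16, adjusted p = 9.76e-07 and 0.65 with an estimated correlation. For the interferon response, edgeR called 0 of 33 tested members (18 higher and 1 lower at an unadjusted p under 0.05, 8 and 0 by DESeq2, 9 rose adjusted over the list alone), with median 0.43, adjusted p = 1.15e-06 and 0.65 with an estimated correlation. Mitochondrially encoded genes were shifted upward, and 1 of 13 tested members rose and 12 did not pass (5 rose adjusted over the list alone), namely mt-Nd5 (0.35, 83.2% unique 31-mers), with median 0.29, adjusted p = 1.31e-05 and 0.582 with an estimated correlation. In the nuclear respiratory chain, 2 of 34 tested members fell and 32 did not pass (9 fell adjusted over the list alone), namely Ndufa5 (−0.36) and Cox7a2 (−0.25), with median −0.11, adjusted p = 2.34e-09 and 0.582 with an estimated correlation. Among epithelial genes, edgeR called 0 of 21 tested members (0 higher and 5 lower at an unadjusted p under 0.05, 0 and 1 by DESeq2, 0 adjusted over the list alone), with median −0.92, adjusted p = 0.00784 and 0.656 with an estimated correlation, a call that ended without Jun replicate 2 (0.134, median −0.57). At the stricter filter the epithelial median turned to 0.075 (adjusted p = 0.656).

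As a list, Hedgehog target genes were called upward, although edgeR called 0 of 11 tested members (3 higher and 0 lower at an unadjusted p under 0.05, 1 and 0 by DESeq2, 0 adjusted over the list alone), with median 0.10, adjusted p = 0.0342 and 0.441 with an estimated correlation, a call that ended without control replicate 1 (0.101), Jun replicate 2 (0.058) or Jun replicate 3 (0.116, median 0.07), and also at the stricter filter (0.0846). Of Hedgehog genes, Gli1 (0.16 ± 0.246, adjusted p = 0.811), Gli2 (0.30 ± 0.114, adjusted p = 0.234), Gli3 (0.22 ± 0.0862, adjusted p = 0.258), Ptch1 (0.19 ± 0.0652, adjusted p = 0.18) and Smo (−0.01 ± 0.0421, adjusted p = 0.928) did not pass. The count of changed genes was 68 without control replicate 2, 54 without control replicate 3, 38 without Jun replicate 1, 46 without Jun replicate 2 and 29 without Jun replicate 3, and 298 without Egr1 replicate 3 and control replicate 2 together. By limma on TPM, where the median gene moved by 0.145, 2203 genes were called, 97.8% higher against 47.5% here, while a length offset gave 37, 35.1% higher, and all 30 libraries 60, 31.7% higher. Of 29 called genes that the naming rule chose, 10 kept their call with each library left out.

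Jun and Egr1 compared directly differed in 64 genes, 15 higher and 49 lower with Jun. Mmp10 (6.56, 88.1% unique 31-mers), Mustn1 (0.83), Npr3 (0.64), Ifi202b (0.53), an interferon-inducible gene, and Adarb1 (0.37), an RNA editing enzyme, were higher with Jun. Vmn1r88 (−2.84, 72.3% unique 31-mers), Mx1 (−2.22), Pmaip1 (−1.72), P2rx7 (−1.33), Id3 (−1.21) and Eng (−1.13) were lower. Groups did not overlap for 17.7% of genes, against 10% by chance. The count was 22 without Egr1 replicate 1, 25 without Egr1 replicate 2, 122 without Egr1 replicate 3, 26 without Jun replicate 1, 36 without Jun replicate 2 and 20 without Jun replicate 3, and 567 without Egr1 replicate 3 and control replicate 2 together. Limma on TPM called 10 genes, 40.0% higher against 23.4% here.

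Epithelial genes were lower with Jun than with Egr1 (median −1.67, adjusted p = 3.92e-10 and 0.393 with an estimated correlation), and edgeR called 0 of 21 tested members (0 higher and 14 lower at an unadjusted p under 0.05, 0 and 3 by DESeq2, 12 were lower adjusted over the list alone). The p53 targets were lower (median −0.06, adjusted p = 0.000959 and 0.393), and 2 of 23 tested members were lower and 21 did not pass (6 were lower adjusted over the list alone). Endothelial markers were lower (median −0.60, adjusted p = 0.016 and 0.393), and 1 of 8 tested members was lower and 7 did not pass (2 were lower adjusted over the list alone). The cell cycle list was higher with Jun (median 0.10, adjusted p = 1.89e-05 and 0.862), and edgeR called 0 of 40 tested members (2 higher and 0 lower at an unadjusted p under 0.05, 0 and 0 by DESeq2, 0 adjusted over the list alone). In the nuclear respiratory chain (median −0.05, adjusted p = 0.0292 and 0.862), edgeR called 0 of 34 tested members (0 higher and 5 lower at an unadjusted p under 0.05, 0 and 0 by DESeq2, 0 adjusted over the list alone). With 1 library left out, these calls held in 6, 6, 2, 5 and 2 of 6 fits, in that order, with medians of 0.029 for the cell cycle and −0.005 for the respiratory chain without Egr1 replicate 1.

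Libraries of this experiment differed in markers of other cell types, which were examined after the data were seen. Epithelial genes summed to 445 CPM in Egr1 replicate 3, to 119 and 100 CPM in Egr1 replicates 1 and 2, and to 75.8 to 109 CPM in the control and Jun libraries. The keratins Krt7 and Krt18 stood at 165 and 106 CPM in Egr1 replicate 3, where Krt7 was at 4.6 and 4.29 CPM in the other Egr1 libraries. Neural markers summed to 176 CPM in control replicate 2 and to 12.8 and 15.5 CPM in the other controls. Map2, a neuronal cytoskeleton gene, was at 53.4 CPM there against 0.193 and 0.124 CPM, and Stmn2 and Dcx stood at 31.6 and 21.4 CPM. Egr1 replicate 3 decides the epithelial call of Egr1 (adjusted p = 0.128 without it). Without it the median of Jun against Egr1 went from −1.672 to −0.93 and the call held (adjusted p = 4.11e-07). Sums were then 119 and 100 CPM against 75.8 to 87.6 CPM with Jun. The stricter filter, which turned the median of Jun against its controls to 0.075, was not run there. A part of low-count members in that call was therefore not tested.

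**Figure D2:**
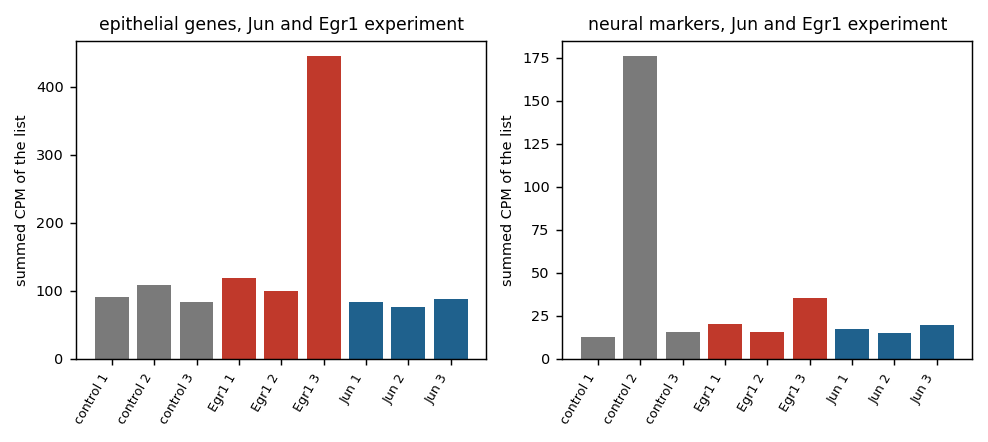
Summed CPM of epithelial genes and of neural markers in each library of the Jun and Egr1 experiment, as bars from 0. Epithelial genes reach 445 CPM in Egr1 replicate 3 and neural markers 176 CPM in control replicate 2.

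Srebf2, known to switch on sterol synthesis, raised several of its target enzymes by small amounts. Msmo1, a sterol demethylase, rose 1.2-fold (log2 fold change 0.26 ± 0.0551, adjusted p = 0.00413, n = 3 per group), and Elovl5, a fatty acid elongase, rose 1.25-fold (0.32 ± 0.0535, adjusted p = 0.000877). Pmvk, another enzyme of the sterol pathway, fell (−0.45 ± 0.0707, adjusted p = 0.000583), and so did Apoe, a lipid carrier and LXR target (−0.69 ± 0.151, adjusted p = 0.00529). In all, 2204 of 12730 tested genes changed, 1099 higher and 1105 lower, but only 72 by over 2-fold, and 501 have under 90% unique 31-mers. The share of tested genes whose groups did not overlap was 35.5%, against 10% by chance.

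The cholesterol list as a whole was not called (adjusted p = 0.292, median 0.09), although 5 of 24 tested members rose, 3 fell and 16 did not pass (7 rose and 3 fell adjusted over the list alone). Idi1 (0.27, 81.2% unique 31-mers) rose with Msmo1, and Tm7sf2 (−0.37, 87.2% unique 31-mers) fell with Pmvk. In fatty acid synthesis and desaturation, 5 of 18 tested members rose and 13 did not pass (5 rose adjusted over the list alone), with median 0.11, adjusted p = 0.00819 and 0.65 with an estimated correlation, a call that ended without control replicate 1 (0.0507). Large rises outside lipid genes were those of Ednra (0.68), the endothelin receptor, Ifi44 (0.75), an interferon-induced gene, and Cenpk (0.66), a kinetochore gene. Large falls were those of P2rx7 (−3.06), Eng (−1.18), Pfdn6 (−0.90), a prefoldin subunit, and Lars2 (−0.85), a tRNA synthetase.

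For the cell cycle, 18 of 40 tested members rose and 22 did not pass (18 rose adjusted over the list alone), with median 0.13, adjusted p = 2.95e-06 and 0.656 with an estimated correlation. Hmmr (0.41), Top2a (0.40) and Kif11 (0.40) are mitotic examples. Among immediate early genes, 9 of 29 tested members fell and 20 did not pass (10 fell adjusted over the list alone), with median −0.25, adjusted p = 3.5e-06 and 0.441 with an estimated correlation. They include Btg2 (−0.51) and Junb (−0.49). In reported AP-1 targets, 6 of 21 tested members fell and 15 did not pass (1 rose and 9 fell adjusted over the list alone), with median −0.16, adjusted p = 0.00564 and 0.65 with an estimated correlation. The cytokine Lif (−0.45) and the ligand Hbegf (−0.38) are among them. For p53 targets, 6 of 21 tested members fell and 15 did not pass (8 fell adjusted over the list alone), with median −0.10, adjusted p = 0.00182 and 0.582 with an estimated correlation. They include Bbc3 (−0.48), Bax (−0.42, 88.9% unique 31-mers) and Cdkn1a (−0.27), the cell cycle inhibitor p21.

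In mitochondrially encoded genes, 8 of 13 tested members rose and 5 did not pass (11 rose adjusted over the list alone), with median 0.36, adjusted p = 2.59e-12 and 0.25 with an estimated correlation. mt-Nd6 (0.43) and mt-Atp6 (0.52, 0.5% unique 31-mers) are examples, and the mitochondrial share of counts was 3.736 ± 0.169% against 3.001 ± 0.169% in the controls (SD, n = 3). In the nuclear respiratory chain, 1 of 34 tested members rose, 10 fell and 23 did not pass (2 rose and 12 fell adjusted over the list alone), with median −0.08, adjusted p = 0.00068 and 0.65 with an estimated correlation. Ndufa2 (−0.70) and Ndufa1 (−0.65) fell most. For the interferon response, 5 of 31 tested members rose and 26 did not pass (5 rose adjusted over the list alone), with median 0.21, adjusted p = 0.00271 and 0.726 with an estimated correlation, a call that ended without control replicate 1 (0.146, median 0.07) or Srebf2 replicate 1 (0.104, median 0.13). Xaf1 (0.45) and Trim30a (0.46, 88.1% unique 31-mers) rose with Ifi44. In primary cilium assembly and transport, 7 of 45 tested members rose, 1 fell and 37 did not pass (7 rose and 1 fell adjusted over the list alone), with median 0.09, adjusted p = 0.0236 and 0.418 with an estimated correlation. The transport genes Ift74 (0.34), Ift88 (0.31) and Kifap3 (0.33) and the BBSome gene Ttc8 (0.40) rose.

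The glycolytic gene Gapdh (−0.26, 71.9% unique 31-mers) and Vegfa (−0.18) fell here, but turned to 0.038 and 0.037 by limma on TPM. Here too Gli1 (0.16 ± 0.209, adjusted p = 0.637), Gli2 (0.04 ± 0.0812, adjusted p = 0.764), Gli3 (0.10 ± 0.0696, adjusted p = 0.371), Ptch1 (0.01 ± 0.0745, adjusted p = 0.968) and Smo (−0.05 ± 0.0461, adjusted p = 0.467) did not pass. The count of changed genes was 996 without control replicate 2, 1132 without Srebf2 replicate 2 and 1411 without Srebf2 replicate 3. The count by limma on TPM was 1019, 66.5% higher against 49.9% here. Of 93 called genes that the naming rule chose, 69 kept their call with each library left out.

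The added sequences and P2rx7 showed how the reporters stood in the transfections. mScarlet, a red fluorescent protein, was at 0 counts in the 6 transduced libraries, which allows up to 0.375 CPM in the shallowest. It fell from 35760 ± 3690 CPM in the Jun and Egr1 controls to 2408 ± 518 with Egr1, 14.9-fold lower (adjusted p = 0.000499), and to 3198 ± 372 with Jun (adjusted p = 0.000655; SD, n = 3). With Srebf2 it fell from 9562 ± 755 to 556.4 ± 54.1 CPM, 17.2-fold lower (adjusted p = 4.66e-15). It did not pass with Prrx1 (13690 ± 2480 CPM) or Snai1 (10260 ± 561 CPM) against 11100 ± 2330 CPM in their controls. P2rx7 stood at 20.5 ± 4.41 CPM with Prrx1 and 5.027 ± 0.911 with Snai1 (control 5.335), at 4.158 ± 0.855 with Jun and 10.34 ± 1.5 with Egr1 (control 16.14 ± 3.61), and at 1.127 ± 0.132 with Srebf2 (control 9.487 ± 1.03). In the transduced libraries it was at 0.1027 ± 0.111 with and 0.2645 ± 0.237 CPM without doxycycline. GFP rose with Prrx1 (0.54, adjusted p = 0.00147) and Snai1 (0.42, adjusted p = 0.0113) and fell with Srebf2 (−0.21, adjusted p = 0.0101). The Srebf2 call of GFP ended without control replicate 2 (0.0543), control replicate 3 (0.0533) or Srebf2 replicate 2 (0.0751), and by limma on TPM (0.0622).

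**Figure D3:**
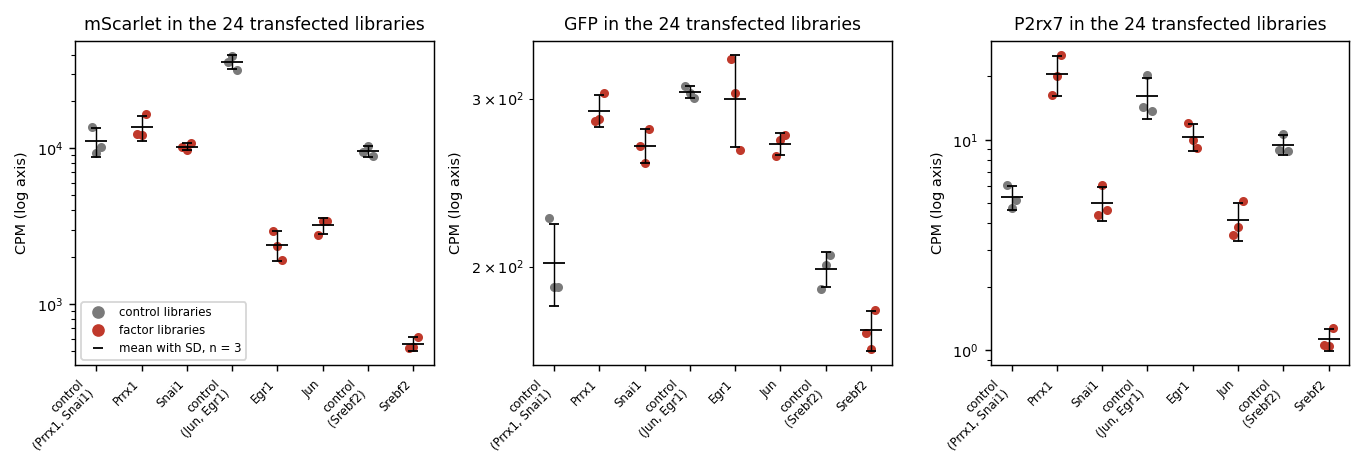
CPM of mScarlet, GFP and P2rx7 in the 24 transfected libraries, 1 point per library. mScarlet falls from 9562 to 556.4 CPM with Srebf2.

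The response to Prrx1 was compared between doxycycline induction and transfection, by a test of the difference itself. Gli2 rose with doxycycline and did not pass with transfection, a log2 difference of 1.51 ± 0.172, adjusted p = 6.48e-05 (n = 3 per group). The difference, induction minus transfection, was positive for Cck (5.12), Adgrg1 (3.84), Aldh1a7 (3.19, 86.2% unique 31-mers), Prelp (2.89), Ptx3 (2.64), Cdh11 (2.05) and Snai2 (1.72). It was negative for Akr1c18 (−4.09), a steroid dehydrogenase, Sdk2 (−3.76), Asdurf (−3.68, 0% unique 31-mers), P2rx7 (−3.63) and Prrx1 (−2.84) itself, which rose 27.5-fold with transfection against 3.86-fold. The calls of P2rx7 and Asdurf ended in 11 and 13 of 18 alternatives, with adjusted p up to 0.497 and 0.149. In all, 612 of 15218 tested genes differed, 302 in favour of induction and 310 of transfection. Across the 12322 genes tested in both, the fold changes had r = −0.018, and genes are not independent replicates. Of 347 genes called in the transfection and tested in the induction, 152 (43.8%) had the same sign. In both, 22 genes were called, 3 higher, 6 lower and 13 opposite (independent lists 7.9 and 3.8, opposite not computed).

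Camera, run for this contrast after the data were seen, called 7 of 28 lists. Cholesterol synthesis and uptake was higher with induction (median 0.28, adjusted p = 1.19e-07 and 0.00503 with an estimated correlation), and 8 of 25 tested members were higher and 17 did not pass (11 were higher adjusted over the list alone). It is the single list called also with an estimated correlation. Mesenchymal genes were higher (median 0.14, adjusted p = 3.82e-05 and 0.109), and 5 of 24 tested members were higher, 1 was lower and 18 did not pass (7 were higher and 1 was lower adjusted over the list alone). Canonical Wnt targets and inhibitors were higher (median 0.51, adjusted p = 0.00314 and 0.0945), and 4 of 10 tested members were higher and 6 did not pass (5 were higher adjusted over the list alone). Immediate early genes were lower (median −0.31, adjusted p = 0.00314 and 0.437), and 1 of 29 tested members was higher, 6 were lower and 22 did not pass (2 were higher and 9 were lower adjusted over the list alone). In the integrated stress and unfolded protein response (median −0.17, adjusted p = 0.0326 and 0.437), 3 of 30 tested members were lower and 27 did not pass (1 was higher and 5 were lower adjusted over the list alone). Mitochondrially encoded genes were higher (median 0.43, adjusted p = 0.0326 and 0.641), and 1 of 13 tested members was higher and 12 did not pass (1 was higher adjusted over the list alone). Nuclear respiratory chain genes were lower (median −0.38, adjusted p = 3.82e-05 and 0.464), and 3 of 34 tested members were lower and 31 did not pass (3 were lower adjusted over the list alone). With 1 library left out, the calls held in 9 of 12 fits for the stress list, 8 for the mitochondrial one (median 0.009 without doxycycline replicate 1 and −0.042 without no-doxycycline replicate 2) and 12 for the others. The count of differing genes was 378 without doxycycline replicate 1, 351 without doxycycline replicate 2, 390 without doxycycline replicate 3, 942 without no-doxycycline replicate 2, 299 without Prrx1 replicate 1, 356 without Prrx1 replicate 2, 381 without Prrx1 replicate 3, 1118 without transfection control replicate 1, 353 without transfection control replicate 2 and 337 without transfection control replicate 3. Among Hedgehog genes, the differences of Gli1 (−0.61 ± 0.416, adjusted p = 0.51), Gli3 (0.16 ± 0.168, adjusted p = 0.695), Ptch1 (0.04 ± 0.236, adjusted p = 0.964) and Smo (0.42 ± 0.174, adjusted p = 0.231) did not pass.

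**Figure D4:**
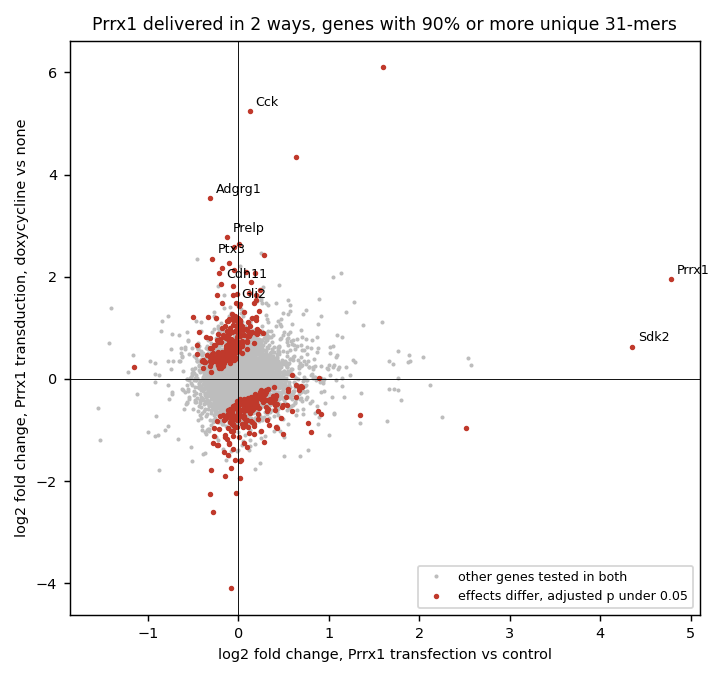
Log2 fold change of each gene with doxycycline (vertical) against that with Prrx1 transfection (horizontal), for genes with at least 90% unique 31-mers. Red points mark genes whose difference had an adjusted p under 0.05, 612 over all tested genes.

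Among the 15 pairs of comparisons, the fold changes of Prrx1 and Snai1 transfection were most alike across genes (r = 0.692, covariance 0.125). Simulated unchanged groups against 3 shared controls gave a mean r of 0.497 (highest 0.652) and covariance of 0.0277 (highest 0.0467). In both, 109 genes were called higher and 46 lower (2.89 and 0.67 for independent lists without shared controls). Nutf2 and Cox5b rose and mt-Nd1 and Ube2c fell in both. Egr1 and Jun, which also share 3 controls, had r = 0.505 (simulated mean 0.5, highest 0.542) and covariance 0.2208 (mean 0.081, highest 0.0916). In both, 6 genes were called higher and 12 lower (0.14 and 0.09 if independent). Ppp1r15a, Mdm2, Plk2, Fosl1 and Atp13a4 fell and Acaca rose in both. Divided so that no control served both factors (6 ways, chosen after the data were seen), Prrx1 and Snai1 had covariances of 0.0904 to 0.1522 and r of 0.177 to 0.319, each above its highest simulated value (up to 0.0208 and 0.183). Over genes with at least 90% unique 31-mers the covariances were 0.0048 to 0.0385. Over all genes Egr1 and Jun had 0.1322 to 0.1696 (highest simulated 0.0339) where Egr1 held control replicate 2. They had −0.1239 to −0.0473 where Jun held it, and −0.3208 to −0.0156 over the unique genes, so no likeness held throughout. Prrx1 and Snai1 were inversely related to Srebf2 (r = −0.258 and −0.289), and Jun and Srebf2 had r = 0.197.

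**Figure D5:**
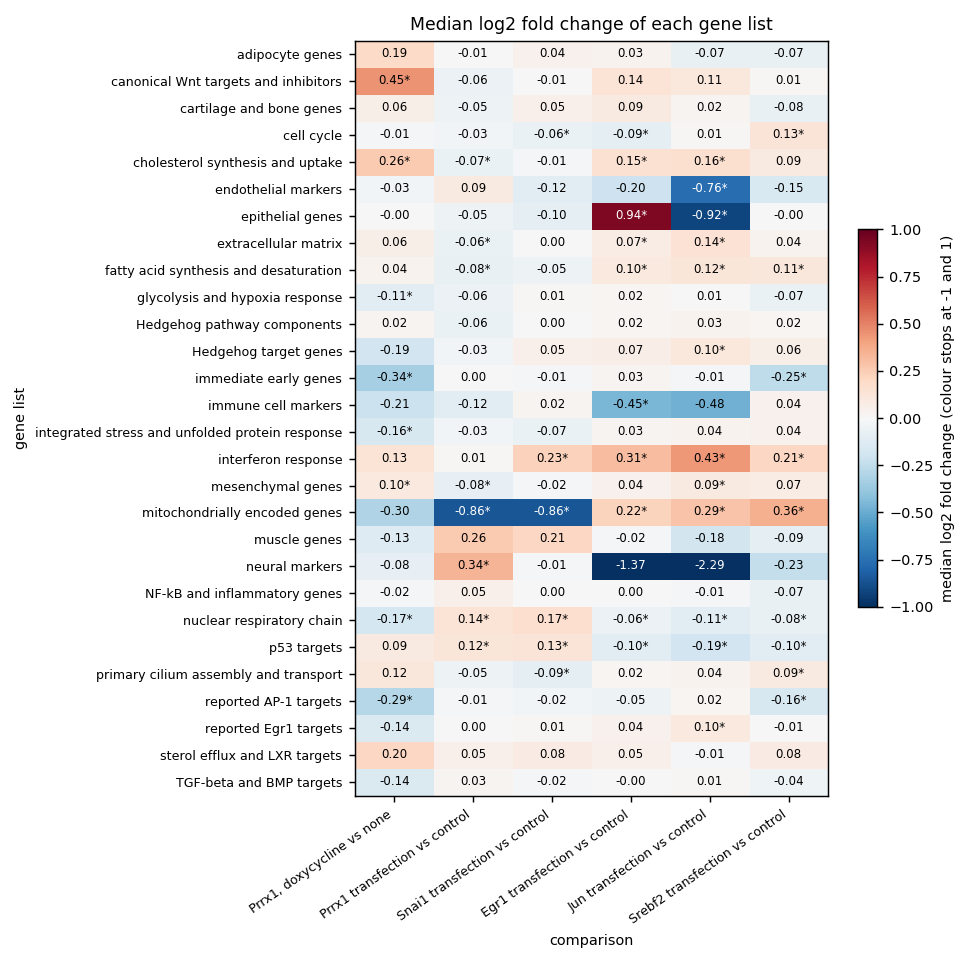
Median log2 fold change of 28 gene lists (vertical) in 6 comparisons (horizontal) as a heat map whose colours stop at −1 and 1. A star marks an adjusted p under 0.05 at the preset correlation, 53 in all.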

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

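Tests chosen only after the result was seen were those of depth, of the P2rx7 ratio and of reporter amount for mScarlet and P2rx7, of doxycycline itself, of control libraries divided between the factors, and of the like-for-like comparison over genes with at least 90% unique 31-mers.

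The response to Prrx1 differed between induction by doxycycline and transfection in 612 genes, by a test of the difference in edgeR. Log2 differences, induction minus transfection, were 5.116 for Cck, 3.844 for Adgrg1, 3.188 for Aldh1a7, 2.889 for Prelp, 2.637 for Ptx3 and 1.506 for Gli2. They were −4.091 for Akr1c18, −3.764 for Sdk2, −3.68 for Asdurf, −3.625 for P2rx7 and −2.842 for Prrx1 itself. Of the called lists, only cholesterol synthesis and uptake kept its call at an estimated correlation (median difference 0.277). Other medians were 0.505 for canonical Wnt targets and inhibitors, 0.144 for mesenchymal genes, −0.313 for immediate early genes and −0.167 for integrated stress genes. The nuclear respiratory chain had −0.379 and mitochondrially encoded genes 0.427 (0.009 or −0.042 with 1 library left out).

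The lower depth of the transduced libraries was tested by thinning the transfection libraries to a fraction of 0.563, which still gave 575 differing genes. A single apart library as the source would lower the count when left out, but it was 942 without no-doxycycline replicate 2. Dose was not decided by the 43.8% of transfection calls with the same sign in the induction, since genes unmoved there take either sign. In the induction 3 integrated stress genes fell (list median −0.163, no call at an estimated correlation). No group has doxycycline without the construct, so its effect cannot be parted from that of Prrx1. Delivery also differs between the experiments, and its part was not tested.

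The likeness of the Prrx1 and Snai1 transfections (covariance of fold changes 0.125) lay above the highest value from simulated noise of shared controls (0.0467) and stayed at 0.1244 without mitochondrially encoded genes. A response to any factor plasmid cannot be judged from the other transfections (lowest r −0.289, Snai1 and Srebf2), as mScarlet fell only there. Over genes with at least 90% unique 31-mers the covariance was 0.0403, 2.1 times the highest simulated (0.0192). There r (0.466) was under its highest (0.522), so a part of reads shared between near-identical genes stays open. A single apart control would leave no likeness with no control shared. Over all genes the covariance was then at least 0.0904 (simulated at most 0.0208), with r above its highest too. Over the unique genes it fell to 0.0048 with control replicate 1 alone for Prrx1 (r = 0.019, highest simulated 0.056), so there an apart control stays open. A common state of these factor libraries, biological or from their handling, stays open, because the simulation covers sampling noise and not a real difference between the 3 controls and the rest.

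mScarlet was lower with Egr1, Jun and Srebf2 (the last 17.2-fold), and P2rx7 with Jun and Srebf2. Depth differed by at most 1.09-fold between a factor group and its control. P2rx7 reads from the mScarlet plasmid alone would keep a fixed ratio, but the ratio of P2rx7 to mScarlet counts was, in thousandths, 4.34 with Egr1 and 1.3 with Jun against 0.448 in their controls, and 2.02 with Srebf2 against 0.991 (at least 2.04 times, with no overlap). P2rx7 was near 0 in the transduced libraries (0.1027 and 0.2645 CPM), another experiment without mScarlet, so a part from the plasmid stays open. Less reporter plasmid and a lowering by the factor cannot be told apart, as no group separates them. The same limit holds for other calls with Egr1, Jun and Srebf2, such as p53 targets and Eng.

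Other splits of the libraries were counted for each of the 9 results. In the comparisons of 3 against 3, 10 splits are too few for a share under 0.05. The real counts were 844 for doxycycline (highest other split 0), 393 for Prrx1 (1), 212 for Snai1 (2), 47 for Egr1 (2), 139 for Jun (0), 2204 for Srebf2 (1), 33 for Snai1 against Prrx1 (1) and 64 for Jun against Egr1 (7). For the difference between the Prrx1 experiments, 1 of 100 drawn splits gave as many as 612 genes, the real one, and the highest other gave 580. Splits that changed the doxycycline labels lose that effect and gave at most 7, and the 12 drawn that kept them gave 252 to 580 and are too few for a share under 0.05, so the count follows the doxycycline labels more than the transfection labels.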

How the results depend on the processing

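Alternatives chosen only after the data were seen were restriction to genes with at least 90% unique 31-mers, leaving out GFP and mScarlet, protein-coding genes only, leaving out Egr1 replicate 3 and control replicate 2 of Jun and Egr1 together, and camera in 3 further contrasts, there also with each library left out. The delivered factors kept direction and call in all 72 alternative fits. Over the named genes, 3319 values kept direction and side of the threshold, 872 lost the call, 5 gained one and 40 turned direction, all of these uncalled genes except Gapdh and Vegfa. Among list tests, 530 values kept the call, 136 lost it and 2 turned. Medians shrank most, among kept calls, for epithelial genes with Egr1 (0.222 at the stricter filter), p53 targets with Prrx1 (0.051 without control replicate 1), the cell cycle with Egr1 (−0.034 without control replicate 3) and p53 targets in Jun against Egr1 (−0.017 without Egr1 replicate 1). A simulated 1.5-fold change was recovered for 14.9% of genes in the difference between the Prrx1 experiments, 35.8% with doxycycline and 79.1% with Srebf2, and depth was not separated from spread. The cause was not tested for any change below unless stated.

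Counts of changed genes moved by over 1.5 times as follows. DESeq2 gave 648 for Prrx1, 533 for Snai1, 420 for Egr1, 857 for Jun, 954 for the difference between the Prrx1 experiments and 420 for Jun against Egr1. Without a filter they were 1326 for doxycycline, 597 for Prrx1, 440 for Snai1 and 63 for Snai1 against Prrx1. The stricter filter gave 252 for Jun and 9 for Snai1 against Prrx1. With a length offset they were 302 for doxycycline, 256 for Prrx1, 7 for Egr1, 37 for Jun, 1157 for Srebf2, 258 for the difference, 9 for Snai1 against Prrx1 and 21 for Jun against Egr1. Counts by limma on TPM were 162 for doxycycline, 367 for Snai1, 1172 for Egr1, 2203 for Jun, 1019 for Srebf2, 245 for the difference, 7 for Snai1 against Prrx1 and 10 for Jun against Egr1. Fits on 6 libraries gave 141 for Prrx1, 64 for Snai1 and 311 for Jun. All 30 libraries together gave 2728 for doxycycline, 94 for Egr1, 60 for Jun and 568 for Srebf2. Only unique genes gave 224 for Prrx1 and 77 for Snai1, with fewer genes tested. Without that pair of libraries they were 355 for Egr1, 298 for Jun and 567 for Jun against Egr1. Camera with an estimated correlation called 0 of 168 tests against 53 at the preset value.

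Leaving out 1 library gave 335 to 1250 genes for doxycycline, 106 to 2639 for Prrx1, 46 to 3062 for Snai1, 10 to 102 for Egr1, 29 to 94 for Jun, 996 to 2329 for Srebf2, 299 to 1118 for the difference between the Prrx1 experiments, 11 to 20 for Snai1 against Prrx1, 20 to 122 for Jun against Egr1, and 45 to 58 list calls. The highest values for Prrx1, Snai1 and the difference came without control replicate 1 of that experiment.

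Replicate numbers were tested as pairs. The 18 same-number correlations lay between −0.149 and 0.043, 0 of them over 0.1, so the numbers do not pair the libraries. With the replicate block, counts moved to 23 for Egr1, 71 for Jun and 34 for Jun against Egr1, and stayed within 1.5 times elsewhere (843 for doxycycline, 401 for Prrx1, 290 for Snai1, 2295 for Srebf2, 641 for the difference, 29 for Snai1 against Prrx1 and 52 list calls).

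Correlations between comparisons moved by over 0.1 in 7 of 45 alternatives. At the stricter filter they were 0.84 for Prrx1 and Snai1, −0.396 for Prrx1 and Srebf2, −0.494 for Snai1 and Srebf2, 0.204 for Egr1 and Srebf2 and 0.36 for Jun and Srebf2. Spearman values were −0.14 for Snai1 and Jun and −0.436 for Snai1 and Srebf2. The sign changed in 9 alternatives, where the main value was at most 0.041 in size.

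These log2 fold changes turned direction. With doxycycline, Ptch1 was −0.179 with a length offset and Gli1 0.002 by limma on TPM. With Prrx1, Gli2 was 0.006 by limma on TPM and −0.092 to 0.008 over left-out libraries (positive without control replicates 2 and 3), Gli3 −0.245 to 0.006 (positive without control replicate 2) and Ptch1 −0.026 (without control replicate 1) to 0.256. With Snai1, Smo was −0.004 without a filter and −0.035 to 0.085 over left-out libraries (negative without control replicates 2 and 3 and Snai1 replicate 3). Gli2 was 0.022 with a length offset and 0.025 by limma on TPM. Gli3 was 0.062 and 0.07 in these and −0.168 to 0.081 over left-out libraries (positive without control replicates 2 and 3 and Snai1 replicate 1). There, mScarlet was −0.211 to 0.079 and Ptch1 −0.089 to 0.19, both turned without control replicate 1, and Gli1 −0.216 (without Snai1 replicate 2) to 0.265. With Egr1, Gli1 was −0.518 with a length offset, −0.214 by limma on TPM and −0.091 to 0.252 over left-out libraries (negative without Egr1 replicate 2 and control replicate 2). Ptch1 was −0.073 with a length offset and Smo 0.083 by limma on TPM, and GFP was 0.113 by limma on TPM and −0.093 to 0.053 (without Egr1 replicate 3). With Jun, Smo was 0.135 by limma on TPM and −0.045 to 0.013 over left-out libraries (positive without control replicates 1 and 3), and the epithelial median was 0.075 at the stricter filter. With Srebf2, Ptch1 was −0.357 with a length offset, −0.263 by limma on TPM and −0.017 to 0.02 over left-out libraries (negative without control replicate 2 and Srebf2 replicate 3). Gapdh was 0.038 and Vegfa 0.037 by limma on TPM, and over left-out libraries Gli1 was −0.029 to 0.349 and Gli2 −0.029 to 0.089, both lowest without Srebf2 replicate 1. In the difference between the Prrx1 experiments the mitochondrial median was −0.042 (without no-doxycycline replicate 2) to 1.259 over left-out libraries.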

Other observations

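The marker sums were computed only after the data were seen. Genes of cartilage and bone summed to 319 to 445 CPM in the 6 transduced libraries and to 2870 to 4050 CPM in the 24 transfected ones, and transduction cannot be parted from experiment here. Neural markers summed to 12.8 to 35.6 CPM in all libraries other than control replicate 2 of Jun and Egr1, and epithelial genes to 48 to 119 CPM in all but Egr1 replicate 3. Epcam, an epithelial adhesion gene, was at 17.2 CPM in that library against 1.62 and 1 CPM in the other Egr1 libraries. Syt1, a synaptic vesicle gene, was at 11.6 CPM in the apart control.

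Some lists were called in none of the 6 comparisons, at the lowest adjusted p given here. They are NF-kB and inflammatory genes (0.174 with Srebf2, median −0.07), TGF-beta and BMP targets (0.391 with doxycycline, median −0.15 and mean 0.03), adipocyte genes (0.315 with Srebf2, median −0.07), cartilage and bone genes (0.498 with Egr1, median 0.09), muscle genes (0.134 with Prrx1, median 0.26), sterol efflux and LXR targets (0.312 with doxycycline, median 0.21) and Hedgehog pathway components (0.243 with Jun, median 0.03 and mean −0.03). In the Srebf2 comparison 5 of 20 tested NF-kB and inflammatory genes fell and 15 did not pass. Of TGF-beta and BMP targets, 2 of 17 rose and 4 fell with doxycycline. Among muscle genes, 1 of 14 rose with Prrx1 and 13 did not pass (3 rose adjusted over the list alone), with Tnnt2, cardiac troponin T, at 0.53. Of sterol efflux and LXR targets, 2 of 8 rose and 1 fell with doxycycline, among them Abca1 at 0.98, a cholesterol pump. Hedgehog target genes had a median of −0.19, a mean of −0.05 and an upward test with doxycycline (adjusted p = 0.491). Neural markers had a median of −1.37 with Egr1 (adjusted p = 0.31) and −2.29 with Jun (0.246), with control replicate 2 in both.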
